A study of Mus musculus with 9 samples.

How the data were processed

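RNA from the hippocampus of female mice aged 9 months was sequenced in 9 libraries, 3 in each of 3 groups. Per the labels' protocols, WT vehicle mice were C57BL/6J, 3xTg vehicle mice carried the 3xTg transgenes of Alzheimer's disease research, and treated 3xTg mice received the compound LP-10d at 10 mg/kg by mouth 4 times a week for 1 month. RNA was extracted with TRIzol and a column kit, and libraries were made with an MGI kit from 300 ng of RNA, per the labels' protocols. The labels do not say that replicates are separate animals, so p-values measure only the spread between these samples.

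The authors deposited raw gene counts for 55471 Ensembl genes, of which 33175 had a count in at least 1 library. The authors also deposited FPKM values for these 33175 genes, with names, biotypes and positions; the ratios of count to FPKM between libraries equalled the ratios of total counts (largest relative deviation 6.66e-16). The genome build is mm10, per the submitters' processing notes. The aligner, the counter and the strand setting are not given in the sources used here, so overlapping, antisense and near-identical genes cannot be told apart in the counts. Of 33051 genes found in GENCODE M21, 32793 had the deposited position. Total counts ran from 16582086 to 19170969 per library. No pair of libraries within a group agreed within sampling noise, as checked by chi-square over genes with a summed count of at least 20.

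Groups were compared with edgeR 4.0.16 in R 4.3.3: genes passing filterByExpr (17396), TMM scaling, 1 fit of all 9 libraries with group means only, the quasi-likelihood test and Benjamini-Hochberg adjustment, with a threshold of 0.05. This edgeR version defaults to the legacy quasi-likelihood; the newer method was set by hand, and the legacy one was run as an alternative. The common biological coefficient of variation was 0.157. Gene lists were tested with camera at a preset correlation of 0.01, over the 42 lists with at least 5 tested genes, and again with an estimated correlation and with fry, which tests whether the genes of a list move one way on balance (limma 3.58.1). Of 705 list genes, 7 had no match by symbol. Beside these models, an exact permutation test of 3 against 3 libraries cannot go below p = 0.1. Levels are CPM computed from the deposited counts with TMM-scaled library sizes, as mean ± SD.

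The groups, tests, gene lists, naming rule and first set of alternatives were fixed before the data were examined. In each comparison the genes named are those past the threshold with groups that do not overlap, a mean CPM of at least 1 and a standard symbol, at most 10 per direction; where fewer than 5 passed, they were completed to 5 by smallest unadjusted p under the same other conditions. From each list described, up to 4 members with the smallest p may be named; App, Mapt, Thy1 and the sex-specific genes are named always, and genes called in both comparisons that share the 3xTg vehicle libraries would be. Some genes that the rule names are not reported here. A gene named outside this rule is said to be chosen after its values were seen.

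The alternatives were other scalings, DESeq2 1.42.0, limma-voom, the legacy test, other filters, a fit of only the 6 libraries compared, a replicate block, leaving out each library, limma-trend on the deposited FPKM with pseudocounts of 0.1 and 1 (fold changes are then on the log2(FPKM + pseudocount) scale, which understates low genes), and a threshold of 1.5-fold added to the test. After seeing the data, 2 more fits were added: a fit without WT vehicle replicate 3 and 3xTg vehicle replicate 2, and a fit with the choroid plexus and striatum list scores as covariates.

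The methods were tested on simulated data, with counts drawn from the real means, spreads and library sizes for 3xTg vehicle against WT vehicle and 200 genes changed. Over the 17193 genes run, edgeR recovered 41.8% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 100% of those changed 4-fold, and 6.75% of its calls were false. DESeq2, over 17396 genes, recovered 56.7%, 92.5% and 98.5%, and 14.9% of its calls were false. The changed genes and the simulated lists were drawn only from genes above a bound on the mean count. Dtl and Tcap, described below, lie under that bound, so recovery of genes with such low counts was not measured. The simulated counts also vary independently between genes and hold no tissue differences between libraries, so recovery in the real data may be lower. In 3xTg vehicle against WT vehicle the choroid plexus list had a median log2 fold change of -2.22, and 0 of its genes passed edgeR's adjusted threshold. Camera found a simulated list of 20 genes raised 1.25-fold at both settings and called none of 42 unchanged lists, in data whose genes vary independently, which real genes do not.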

Results

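Gene expression was counted in the hippocampus of WT vehicle, 3xTg vehicle and LP-10d-treated 3xTg mice, with 3 libraries per group and total counts of 16582086 to 19170969 per library. The 3xTg line carries, among its transgenes, mutant human APP and MAPT under the Thy1 promoter. LP-10d is described in the series title only as acting on 3 kinases, which the labels do not name.

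The transgene-related genes were examined first. App stood at 1905 ± 291 CPM in WT vehicle, 1653 ± 117 in 3xTg vehicle and 1676 ± 37.6 in treated libraries (SD, n = 3 each). Mapt was at 641 ± 28.5, 629 ± 7.48 and 619 ± 12.8 CPM in the same order. Neither passed in any comparison with edgeR or DESeq2, and reads from human sequences may not be counted at the mouse genes. Thy1 was at 768 ± 328, 1250 ± 258 and 925 ± 234 CPM (SD, n = 3 each). It ran from 517 to 1139 CPM in WT vehicle and was at 656 CPM in treated replicate 2. Xist, expressed from the inactive X, lay between 357 and 562 CPM in all 9 libraries, which are labelled female. Counts of Ddx3y, Eif2s3y and Kdm5d were 0 in 8 libraries, where the limit that a count of 0 allows is 3 counts, and 2, 4 and 3 in 3xTg vehicle replicate 1.

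Libraries differed in markers of tissue beside the hippocampus, of which Ttr, Penk and Tcf7l2 are named here after their values were seen. Drd2, the dopamine D2 receptor of the striatum, was at 79.8 CPM in 3xTg vehicle replicate 2 and between 2.58 and 9.60 CPM in the other libraries. Penk was at 165 CPM there and between 11.1 and 34.6 CPM elsewhere. Tcf7l2, a thalamic marker, reached 54.3 CPM in WT vehicle replicate 3 and 26.6 CPM in 3xTg vehicle replicate 2. Ttr, the main transcript of the choroid plexus, ran from 33.4 to 4016 CPM in WT vehicle, 26.6 to 837 CPM in 3xTg vehicle and 18.8 to 2397 CPM in treated libraries. In WT vehicle replicate 3 the mitochondrial genes took 5.04% of counts, against 2.28% to 2.86% in the others.

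**Figure D1:**
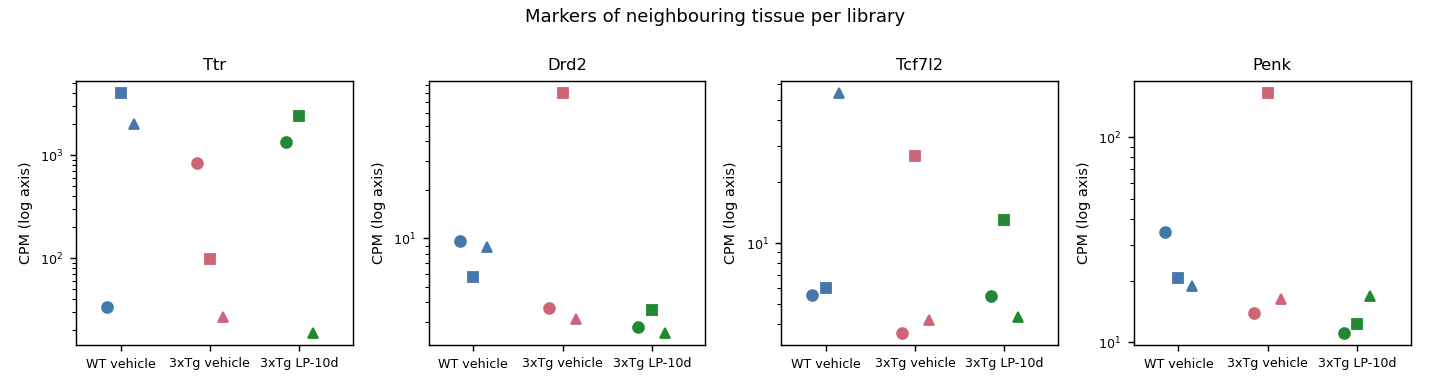
CPM on a log axis of Ttr (choroid plexus), Drd2, Tcf7l2 and Penk in each library, coloured by group; circles, squares and triangles are replicates 1, 2 and 3. Drd2 and Penk stand apart in 3xTg vehicle replicate 2, at 79.8 and 165 CPM.

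The first comparison asked how the 3xTg hippocampus differs from the wild type. In this and the third comparison, the 3xTg line may differ from WT vehicle mice in strain background as well as in its transgenes. These groups cannot separate strain from transgenes, so no difference from the wild type can be assigned to the transgenes alone. Libraries also differed in markers of tissue beside the hippocampus, so differences in dissection cannot be set aside for lists of region and cell type genes. Plxnd1, a semaphorin receptor of axon guidance and vessel growth, rose in 3xTg vehicle, from 57.03 ± 7.60 to 133 ± 9.18 CPM (SD, n = 3 each). With camera's preset correlation, genes of cholesterol biosynthesis, neuropeptides and GABAergic neurons were higher as groups, and all 3 calls were lost with an estimated correlation (adjusted p = 0.369 for each). Interferon-response, dentate gyrus, CA3 and CA2, postsynaptic and oligodendrocyte precursor genes were lower as groups at the preset correlation, and these calls were lost too (adjusted p = 0.461, 0.369, 0.369, 0.461 and 0.369 with an estimated correlation).

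Plxnd1 (ENSMUSG00000030123, mm10 chromosome 6, 115954811 to 115995005) had a log2 fold change of 1.22 ± 0.12 (SE), and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.0199. It was the 1 gene of 17396 that passed. Its adjusted p ran over the threshold without WT vehicle replicate 1 (0.0985) or 3 (0.0653), 3xTg vehicle replicate 2 (0.150) or 3 (0.172), or treated replicate 1 (0.0757), and in a fit of the 6 libraries alone (0.0542), with log2 fold changes of 1.13 to 1.22 in these fits; over all alternatives it ran from 3.03e-16 to 0.201. At an unadjusted p under 0.05 edgeR counted 2449 genes, where 870 come by chance; DESeq2 called 339 genes, 231 of them higher, and limma-voom 1. The groups did not overlap in 17.4% of genes, against 10% by chance.

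The genes next in rank did not pass edgeR's adjusted threshold. Dtl, a subunit of a ubiquitin ligase of the replication checkpoint (ENSMUSG00000037474, chromosome 1, 191537356 to 191575544), was at 1.08 ± 0.24 CPM in WT vehicle and 3.85 ± 0.60 CPM in 3xTg vehicle (SD, n = 3 each; edgeR adjusted p = 0.064). Bmp3, the neuronal tubulin Tubb3 and Tcap had log2 fold changes of 1.31, 0.61 and 1.92. Among lower genes, the splicing-related Hnrnpa3 was at 77.05 and 49.98 CPM in WT vehicle and 3xTg vehicle, and the NAD-consuming enzyme Cd38 at 8.09 and 4.08 CPM. Sh3bgrl, Bcl6b and Ifi203 had log2 fold changes of -0.53, -1.15 and -1.53, and edgeR adjusted p ran from 0.064 to 0.0844 over these 9 genes.

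**Figure D2:**
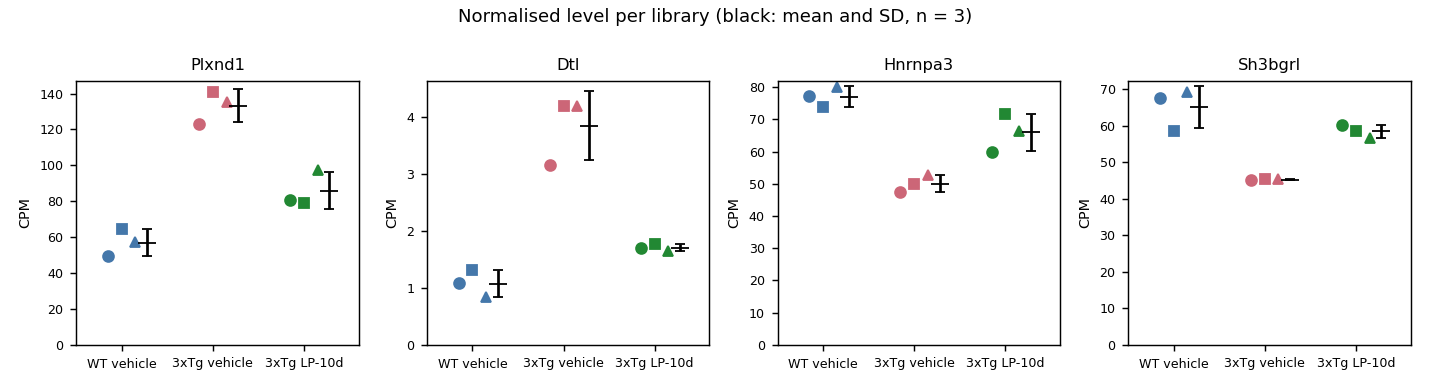
CPM of Plxnd1, Dtl, Hnrnpa3 and Sh3bgrl in each library, coloured by group, with the mean and SD (n = 3) in black; circles, squares and triangles are replicates 1, 2 and 3. The 3xTg vehicle libraries lie apart from the other 6 for all 4 genes, with Plxnd1 means of 57.03, 133 and 85.8 CPM; only Plxnd1 in 3xTg vehicle against WT vehicle passed edgeR's test.

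Of the 42 lists, 19 passed with camera's preset correlation in this comparison, 7 higher and 12 lower, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.369. No single member of a list passed over all genes. Cholesterol biosynthesis had 16 of 19 genes higher, with a median log2 fold change of 0.23 (camera adjusted p = 9.69e-05; adjusted p = 0.369 with an estimated correlation). Adjusted over the list alone 5 of them rose, among them Fdft1, the squalene synthase (log2 fold change 0.38). Neuropeptide genes were higher in 14 of 15, and 5 rose adjusted over the list alone, with Adcyap1 at 1.27 and Vip at 0.92 (camera adjusted p = 0.000145; adjusted p = 0.369 with an estimated correlation). The striatal markers stood out in 3xTg vehicle replicate 2 of this same group. Adjusted over the list alone, 2 GABAergic, 3 cortical and 2 haemoglobin and leukocyte genes rose. GABAergic genes were higher in 13 of 18, led by Reln at 0.60, and cortical markers in 9 of 12, led by Lamp5 at 0.88 and Cux2 at 1.06 (camera adjusted p = 0.00654 and 0.00862; adjusted p = 0.369 and 0.461 with an estimated correlation). Haemoglobin and leukocyte genes were higher in 6 of 7, led by Hba-a1 at 2.06 (camera adjusted p = 0.000271; adjusted p = 0.369 with an estimated correlation). The GABAergic call was lost without WT vehicle replicate 2 (camera adjusted p = 0.128), with a median of 0.0673 in place of 0.142. The cortical call was lost without WT vehicle replicate 1 or 2 or 3xTg vehicle replicate 3 (camera adjusted p = 0.1, 0.129 and 0.113). Cortical medians were then 0.394, 0.602 and 0.249 in place of 0.579. Without 3xTg vehicle replicate 2 the neuropeptide and cortical medians were 0.268 and 0.275 in place of 0.772 and 0.579, and the haemoglobin and leukocyte median of 0.894 was 1.45 without WT vehicle replicate 2 and 0.547 without WT vehicle replicate 3, with these calls kept.

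All 17 interferon-response genes were lower, with Trim30a at -0.82 and Oasl2 at -0.61 (camera adjusted p = 0.000669; adjusted p = 0.461 with an estimated correlation). Their scores per library were 0.32, 0.24 and -0.56 in WT vehicle and -0.41 to -0.36 in 3xTg vehicle. Of these, 0 fell adjusted over the list alone. Dentate gyrus genes were lower in 10 of 12, led by Dock10 at -0.44, and CA3 and CA2 genes in 10 of 11, led by Amigo2 at -0.67 (camera adjusted p = 0.000145 and 9.13e-05; adjusted p = 0.369 for both with an estimated correlation). Dentate gyrus scores were -0.267, -0.802 and -0.266 in 3xTg vehicle replicates 1, 2 and 3, and the thalamus and striatum score of replicate 2 was 2.37. CA3 and CA2 scores were -0.271, -0.279 and -0.579, and replicate 3 had the highest cortical score, 0.669. Postsynaptic genes were lower in 17 of 20, with the AMPA receptor subunit Gria1 at -0.50 (camera adjusted p = 0.000342; adjusted p = 0.461 with an estimated correlation). Adjusted over the list alone, 1 dentate gyrus gene, 2 CA3 and CA2 genes and 3 precursor genes fell, and 0 postsynaptic, myelin and choroid plexus genes. Oligodendrocyte precursor genes were lower in 12 of 12 and myelin genes in 14 of 16 (camera adjusted p = 0.000533 and 0.000241; adjusted p = 0.369 and 0.461 with an estimated correlation). Choroid plexus genes were lower in 14 of 14, with a median of -2.22, while their scores ran from -2.39 to 1.43 within WT vehicle (camera adjusted p = 2.86e-05; adjusted p = 0.461 with an estimated correlation). Immediate early genes were lower in 17 of 19, led by Nr4a3 at -0.81 (camera adjusted p = 0.00314; adjusted p = 0.461 with an estimated correlation). Neuroblast genes (9 of 12 lower, led by Neurod1), chaperones (13 of 16, led by Hspa1b at -0.59) and reactive astrocyte genes (15 of 19, led by Amigo2) also passed (camera adjusted p = 0.0172, 0.00522 and 0.00583; adjusted p = 0.461, 0.369 and 0.369 with an estimated correlation). Amigo2 stands in both the CA3 and CA2 list and the reactive astrocyte list, so its fall is not separate evidence for each. Adjusted over the list alone, 3 immediate early, 4 neuroblast, 0 chaperone and 5 reactive astrocyte genes fell and 1 reactive astrocyte gene rose. Single libraries ended 4 of these calls: interferon response without WT vehicle replicate 1 or 2 (camera adjusted p = 0.1 and 0.0555), neuroblasts and reactive astrocytes without WT vehicle replicate 2 (0.229 and 0.0645), and immediate early genes without 3xTg vehicle replicate 2 (0.0534). Without WT vehicle replicate 3 the medians of dentate gyrus, postsynaptic, immediate early and chaperone genes moved from -0.485, -0.226, -0.261 and -0.152 to -0.307, -0.108, -0.144 and -0.0679; the dentate gyrus median was -0.303 without 3xTg vehicle replicate 2, and the myelin and reactive astrocyte medians -0.182 and -0.179 in place of -0.293 and -0.289 without 3xTg vehicle replicate 3. The interferon-response median of -0.483 was -0.188 without WT vehicle replicate 1 and -0.747 without WT vehicle replicate 3, and the neuroblast median of -0.224 was -0.429 without WT vehicle replicate 1 and -0.133 without 3xTg vehicle replicate 2.

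Respiratory chain genes went both ways: those encoded in mitochondria were lower in 11 of 12, and those of the nucleus higher in 28 of 32, as were ribosomal protein genes in 26 of 30 (camera adjusted p = 0.000683, 0.00282 and 0.0211; adjusted p = 0.466, 0.611 and 0.698 with an estimated correlation). WT vehicle replicate 3 scored 0.63, -0.34 and -0.60 for these lists. Without it the ribosomal median turned from 0.16 to -0.08 and the mitochondrial and nuclear calls were lost (camera adjusted p = 0.261 and 0.812, medians -0.0951 and 0.00438). The ribosomal call was also lost without 3xTg vehicle replicate 1 or 3 (camera adjusted p = 0.0855 and 0.0554), and its median was 0.311 without WT vehicle replicate 2. The lists of disease-associated and homeostatic microglia, amyloid processing, tau and its kinases, and the DYRK, CLK, GSK3 and HIPK kinases did not pass, with median log2 fold changes of -0.09, 0.04, -0.06, 0.04 and -0.02 (camera adjusted p = 0.0908, 0.906, 0.353, 0.345 and 0.305). Of 18 disease-associated microglia genes, 4 fell adjusted over the list alone.

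The second comparison asked what LP-10d changed in 3xTg mice. No gene passed edgeR's adjusted threshold. As groups, with camera's preset correlation, cholesterol biosynthesis, circadian clock, immediate early and glucocorticoid-response genes were lower in treated libraries, and myelin, oligodendrocyte precursor and choroid plexus genes were higher. None of these calls held with an estimated correlation (adjusted p = 0.189 to 0.639). The clock and glucocorticoid lists were set up as lists of timing. Differences between groups in time of day or handling at collection were not tested, here or in the third comparison. At an unadjusted p under 0.05 edgeR counted 504 genes, fewer than the 870 of chance. DESeq2 called 1 gene, Plxnd1, lower with adjusted p = 0.0399, and limma-voom 0. The groups did not overlap in 11.6% of genes, against 10% by chance.

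Plxnd1 was at 85.8 ± 10.2 CPM and Dtl at 1.71 ± 0.07 CPM in treated libraries (SD, n = 3 each), with log2 fold changes of -0.63 ± 0.12 and -1.17 ± 0.20 (SE). Depp1, the immediate early gene Egr4 and the cell cycle inhibitor Cdkn1a were at -1.33, -0.40 and -0.81. Hnrnpa3, Sh3bgrl, Amigo2, the oligodendrocyte factor Olig2 and Cetn4 were at 0.40, 0.37, 0.62, 0.40 and 0.93. None passed edgeR's test with Benjamini-Hochberg adjustment (adjusted p = 1 for each).

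Of the 42 lists, 11 passed at the preset correlation, 4 higher and 7 lower, and 0 with an estimated one. All 19 cholesterol biosynthesis genes were lower, with a median of -0.155 (camera adjusted p = 5.74e-10; adjusted p = 0.250 with an estimated correlation). Adjusted over the list alone, 0 of them fell. All 16 clock genes were lower, with Per1 at -0.32 and Cry1 at -0.33 (camera adjusted p = 1.36e-05; adjusted p = 0.294 with an estimated correlation). Immediate early genes were lower in 14 of 19, and adjusted over the list alone Egr4 and Fosb (-0.58) fell (camera adjusted p = 9.05e-05; adjusted p = 0.540 with an estimated correlation). Their scores were -0.803, -0.215 and -0.31 in treated replicates 1, 2 and 3 and -0.362 to -0.00374 in 3xTg vehicle, so replicates 2 and 3 lay within the vehicle range. Without treated replicate 1 the immediate early median moved from -0.243 to -0.0561 and the call was lost (camera adjusted p = 0.352), as it was without 3xTg vehicle replicate 3 (0.12). Glucocorticoid-response genes were lower in 12 of 15, and Cdkn1a fell adjusted over the list alone (camera adjusted p = 0.000214; adjusted p = 0.189 with an estimated correlation). Thalamic and striatal markers were lower in 13 of 14, with Drd2 at -3.27, and neuropeptides in 13 of 15, with Pdyn at -0.98 (camera adjusted p = 2.6e-06 and 5.8e-05; adjusted p = 0.540 and 0.322 with an estimated correlation). Without 3xTg vehicle replicate 2 their medians moved from -1.74 to -0.185 and from -0.585 to -0.17, with camera adjusted p = 0.84 and 0.0298. Haemoglobin and leukocyte genes were lower in 7 of 7 (camera adjusted p = 0.000571; adjusted p = 0.540 with an estimated correlation). Myelin genes were higher in 16 of 16, precursor genes in 11 of 12, choroid plexus genes in 14 of 14 and CA3 and CA2 genes in 8 of 11 (camera adjusted p = 0.000398, 0.00241, 5.4e-06 and 0.00121; adjusted p = 0.639, 0.540, 0.546 and 0.356 with an estimated correlation). Choroid plexus scores ran from -3.02 to 0.805 in treated and from -3.08 to -0.372 in 3xTg vehicle libraries, and the median of 1.27 was 0.568 without treated replicate 2 (camera adjusted p = 0.0488) and 2.22 without 3xTg vehicle replicate 1. Olig2 and Amigo2 rose adjusted over the list alone, and 0 clock, striatal, neuropeptide, myelin and choroid plexus genes passed. Without treated replicate 1 the myelin median turned from 0.16 to -0.04 (camera adjusted p = 0.995) and the precursor call was lost (0.101). Without 3xTg vehicle replicate 3 the myelin, precursor and CA3 and CA2 calls were lost (camera adjusted p = 0.251, 0.126 and 0.0606) and the clock and haemoglobin and leukocyte medians moved from -0.165 to -0.101 and from -0.611 to -0.369. The myelin median of 0.156 was 0.25 without treated replicate 2, the precursor median of 0.0852 was 0.156 and the glucocorticoid-response median of -0.0972 was -0.191 without treated replicate 3, and the CA3 and CA2 median of 0.0596 was 0.221 without 3xTg vehicle replicate 1.

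**Figure D3:**
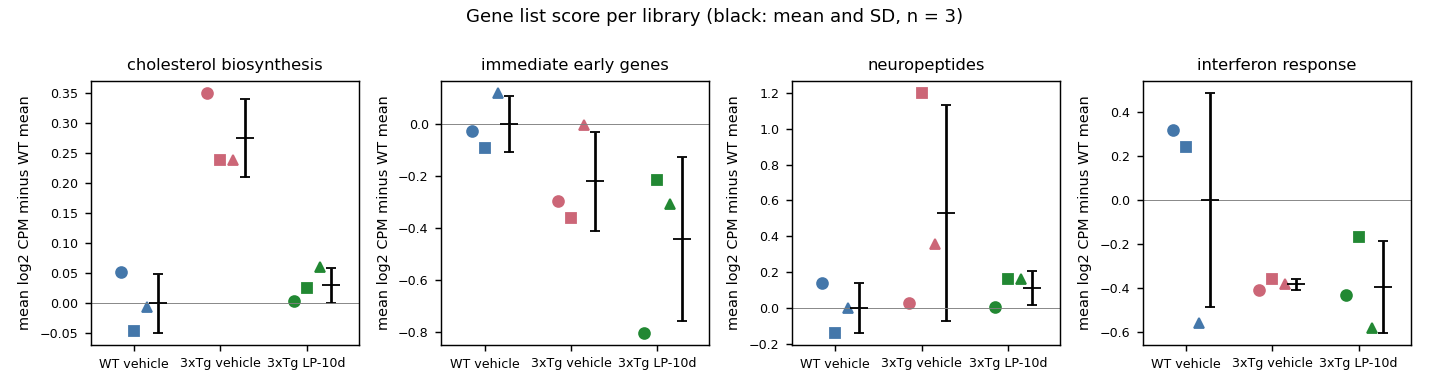
Score per library (mean log2 CPM of the list's genes minus the WT vehicle mean) for 4 gene lists, coloured by group, with the mean and SD (n = 3) in black; circles, squares and triangles are replicates 1, 2 and 3. Cholesterol biosynthesis scores were 0.24 to 0.35 in 3xTg vehicle and -0.05 to 0.06 in the other 6 libraries.

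The third comparison asked where treated mice stand against the wild type. No gene passed edgeR's adjusted threshold; 1523 had an unadjusted p under 0.05, DESeq2 called 46 and limma-voom 0. The groups did not overlap in 14.4% of genes, against 10% by chance. As groups, with camera's preset correlation, immediate early and glucocorticoid-response genes were lower in treated mice, and so were interferon-response, dentate gyrus and postsynaptic genes. None of these calls held with an estimated correlation (adjusted p = 0.543 and 0.0711 for the first pair and 0.615 for the others). Egr4 was at 43.1 ± 1.59 CPM in WT vehicle and 26.4 ± 2.80 CPM in treated libraries (SD, n = 3 each), a log2 fold change of -0.71 ± 0.09 (SE; edgeR adjusted p = 0.299).

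Fosb, Tent5a, Tm6sf2 and Muc3a were at -0.89, -0.94, -1.07 and -0.60, and the microtubule-binding ubiquitin ligase Mid1, Vwa5b2, Sec14l3, Camk2n2 and Rprm at 3.19, 0.65, 2.16, 0.47 and 0.63, none passing edgeR's test (adjusted p = 0.416 for each). Mid1, which spans the pseudoautosomal boundary of the X, was at 8.72 CPM in treated replicate 2 and 40.1 and 35.4 CPM in replicates 1 and 3. Without replicate 2 its edgeR adjusted p was 0.0146, and over all alternatives it ran from 0.000692 to 0.853.

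Of the lists, 11 passed at the preset correlation, 2 higher and 9 lower, and 0 with an estimated one. Immediate early genes were lower in 16 of 19, with a median of -0.44, and adjusted over the list alone 8 fell (camera adjusted p = 1.76e-10; adjusted p = 0.543 with an estimated correlation). Glucocorticoid-response genes were lower in 13 of 15, and 4 fell adjusted over the list alone, led by Per1 at -0.49 and Sgk1 at -0.74 (camera adjusted p = 6.55e-06; adjusted p = 0.0711 with an estimated correlation; fry adjusted p = 0.0105). Interferon-response genes were lower in 17 of 17, dentate gyrus genes in 12 of 12 and postsynaptic genes in 18 of 20 (camera adjusted p = 3.51e-05, 1.14e-05 and 1.71e-05; adjusted p = 0.615 for each with an estimated correlation). The DYRK, CLK, GSK3 and HIPK kinases were lower in 14 of 17, led by Clk1 at -0.29 (camera adjusted p = 0.0161; adjusted p = 0.615 with an estimated correlation). Mitochondrially encoded, CA3 and CA2 and reactive astrocyte genes were lower in 11 of 12, 10 of 11 and 14 of 19, and nuclear respiratory and ribosomal genes higher in 30 of 32 and 27 of 30 (camera adjusted p = 0.0252, 0.0252, 0.0481, 3.21e-06 and 2.51e-05; adjusted p = 0.628, 0.615, 0.615, 0.615 and 0.628 with an estimated correlation). Without WT vehicle replicate 3 the mitochondrially encoded median turned from -0.42 to 0.05 (camera adjusted p = 0.394), the ribosomal call was lost (0.992), and the nuclear respiratory and postsynaptic medians moved from 0.203 to 0.0531 and from -0.25 to -0.114. Calls were also lost without WT vehicle replicate 1 for interferon-response and CA3 and CA2 genes (camera adjusted p = 0.0599 and 0.238), without WT vehicle replicate 2 or treated replicate 3 for reactive astrocyte genes (0.24 and 0.267), and without treated replicate 1 for mitochondrially encoded genes (0.135), where the immediate early median was -0.281. The CA3 and CA2 median of -0.169 was -0.012 without WT vehicle replicate 1, and without WT vehicle replicate 2 the CA3 and CA2, mitochondrially encoded and ribosomal medians were -0.289, -0.652 and 0.374 in place of -0.169, -0.415 and 0.209.

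The first and second comparison share the 3xTg vehicle libraries with opposite sign. No gene was called in both. At unadjusted p under 0.05, 272 genes moved in opposite directions, against a mean of 182 (158 to 204) in 20 simulations of unchanged groups; per direction, 188 were higher then lower and 84 lower then higher, where independent lists give 23.7 and 11.7. The simulations gave 83.2 (72 to 101) and 99 (73 to 121), where independent lists of their sizes give 10.4 in each direction. The real lists were larger than the simulated ones in the first direction, so the counts do not show more opposite movement than shared libraries give. Across genes, which are not independent replicates, the log2 fold changes correlated at -0.593 (simulated mean -0.497, -0.528 to -0.474). Their covariance was -0.0672 (simulated mean -0.037, -0.04 to -0.0345). Both values lay beyond all 20 simulations. Sharing the 3xTg vehicle libraries alone gave -0.497 and -0.037 in unchanged groups, so much of both observed values comes from sharing. The simulated genes vary independently, and 3 shared libraries cannot be split into pairs, so the rest may come from these libraries too.

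With 1 called gene the side-by-side count of called genes is 0 and tests nothing. Among the 200 genes with the smallest p, a set chosen after seeing the data, 14 had a neighbouring tested gene in the set for 3xTg vehicle against WT vehicle, against a mean of 4.57 in 10000 random draws (one-sided permutation p = 0.0072, adjusted p = 0.0313 over 10 such tests). For treated against WT vehicle the count was 13 (one-sided permutation p = 0.0094, adjusted p = 0.0313), and for treated against 3xTg vehicle 4 (one-sided permutation p = 0.67). Among the 337 genes DESeq2 called for 3xTg vehicle against WT vehicle with a position on the autosomes or the X it was 26, against a mean of 13 (adjusted p = 0.0325 by permutation), and among its 46 calls for treated against WT vehicle it was 4, against a mean of 0.23 (adjusted p = 0.0313 by permutation). Within 1 Mb, 10 of these 46 had a partner, against a mean of 3.12 in 1000 draws (adjusted p = 0.046 by one-sided permutation), and 149 of the 337, against a mean of 127 (adjusted p = 0.0517). Among the sets of 200, 57, 60 and 62 had one within 1 Mb, in the order of the comparisons, against means of 51, 50.8 and 51.2 (adjusted p = 0.278, 0.162 and 0.141). Segments of differing strain background could place changed genes side by side in comparisons with WT vehicle and not within the 3xTg line. The side-by-side counts of the sets of 200 follow that pattern, and their counts within 1 Mb do not. Treated against 3xTg vehicle is a weak reference, however: edgeR counted 504 genes at unadjusted p under 0.05 there, fewer than the 870 of chance. Its 200 genes may lie near random draws whatever the cause elsewhere. The 2 comparisons with WT vehicle share the WT vehicle libraries, and overlapping genes were not set aside in the draws. These counts therefore cannot decide on strain. Strain background stays open as a cause in both comparisons with WT vehicle.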

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

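The Y-linked genes Ddx3y, Eif2s3y and Kdm5d gave 9 counts (2, 4 and 3) in 3xTg vehicle replicate 1 and 0 in the other 8 libraries, although the labels state female mice throughout; the sum lies above the 3 counts that a count of 0 allows, which covers counting error only. Xist in that library was at 490.2 CPM. No explanation was tested.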

How the results depend on the processing

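The fit with the choroid and striatum scores, the fit without WT vehicle replicate 3 and 3xTg vehicle replicate 2 together, and the sets of 200 genes and of DESeq2's calls were chosen after seeing the data. The count of called genes in 3xTg vehicle against WT vehicle was 1. It was 3 with no filter, 0 with the choroid and striatum covariates, 339 with DESeq2, and 8, 3 and 17 with limma-trend on FPKM (pseudocount 0.1, pseudocount 1, and 0.1 with no filter). Without single libraries it ran from 0 to 11: 11 without WT vehicle replicate 2, 4 without 3xTg vehicle replicate 1 or treated replicate 2, and 0 without WT vehicle replicate 1, 3xTg vehicle replicate 2 or 3 or treated replicate 1. Plxnd1 was not the 1 gene called without WT vehicle replicate 3, in the 6 libraries alone, or without WT vehicle replicate 3 and 3xTg vehicle replicate 2. For treated against 3xTg vehicle, 0 became 1 with DESeq2 and 8 with unfiltered FPKM. For treated against WT vehicle, 0 became 46 with DESeq2, 1 with FPKM (pseudocount 0.1), 7 with unfiltered FPKM and 2 without treated replicate 2. Genes called in opposite directions were 0, but 272 at unadjusted p 0.05, 1 with DESeq2 and 6 with unfiltered FPKM. Side-by-side genes were 0 among calls, 14 among the 200 with the smallest p and 26 among DESeq2's calls. The cause of these differences was not tested.

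Lists past the threshold (19, 11 and 11) were 0, 0 and 0 with an estimated correlation and 0, 0 and 2 with fry. The 2 were glucocorticoid response and cytokines and NF-kB targets (fry adjusted p = 0.0105 for each). The cytokine list had not passed with camera (camera adjusted p = 0.0746). Of the lists past camera's threshold, 9, 5 and 5 lost the call without some single library of the comparison. The count of the second comparison ran from 7 (without 3xTg vehicle replicate 3) to 15 without single libraries. That of the third ran from 11 to 19, with 18 without WT vehicle replicate 3, 19 without treated replicate 2 and 19 without the pair of libraries. The replicate block gave 1, 0 and 0 called genes and 19, 11 and 15 lists. Same-numbered libraries correlated at -0.178 to 0.375 in their deviations from group means, and 2 of 9 libraries correlated best with their own number, so the numbers were not taken as pairs.

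Of the comparisons of named genes with their alternatives, 2663 kept direction and side of the threshold, 47 passed only in the alternative, 8 (all Plxnd1) passed only before it and 8 turned sign, none of these 8 called in either fit. Mapt in 3xTg vehicle against WT vehicle was 0.0163, 0.0161 and 0.0163 in the FPKM fits. Without single libraries App and Xist, treated against 3xTg vehicle, ran from -0.0371 to 0.0579 and from -0.157 to 0.00912, and mt-Nd1, treated against WT vehicle, from -0.78 to 0.0532. Without the pair of libraries Xist was 0.0141 and mt-Nd1 0.0532. List medians that turned sign without single libraries were ribosomal proteins in 3xTg vehicle against WT vehicle (-0.078 to 0.311, passing as lower without WT vehicle replicate 3), myelin in treated against 3xTg vehicle (-0.0361 to 0.25) and mitochondrially encoded genes in treated against WT vehicle (-0.652 to 0.0514). Without the pair of libraries the first was -0.0444 and the last 0.0513. With the covariates the choroid plexus and striatal calls were lost, with medians near 0 of the same sign (-0.0666, 0.0832 and -0.0449; camera adjusted p = 0.704, 0.519 and 0.839), as fitting these lists' own scores brings about; camera's direction, set against other genes, turned.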

Other observations

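The tests in this part were chosen after the result was seen, except the splits of libraries; for the covariate fit of cholesterol genes and the test of neighbouring genes, both added after seeing the data, the bounds were set before their values were seen. A search of 3289 Gene Ontology terms of the deposited annotation with camera found cholesterol biosynthetic process higher in 3xTg vehicle than in WT vehicle (28 genes, median log2 fold change 0.24, adjusted p = 0.0325) and lower in treated than in 3xTg vehicle (median -0.12, adjusted p = 0.00377). Isoprenoid biosynthetic process ranked first in the first of these comparisons (15 genes, median 0.272, camera adjusted p = 0.00105) and did not pass in the second (camera adjusted p = 0.0797). With an estimated correlation both terms had adjusted p = 0.972 and 0.999 in the 2 comparisons. The cholesterol term names the same pathway as the cholesterol list and used the same libraries, so it adds no independent support. In treated against WT vehicle, 34 terms passed and 0 with an estimated correlation, among them assembly of respiratory complex I (48 genes, median 0.27).

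The pituitary hormone genes Prl, Gh and Pomc, looked up after other values were seen, reached 31.7, 20.3 and 108 CPM in 3xTg vehicle replicate 2, and Prl was also at 17.25, 21.9, 30.6 and 14.8 CPM in WT vehicle replicates 1 and 3 and treated replicates 2 and 3. Pomc is a member of the neuropeptide list. In 3xTg vehicle replicate 3 and treated replicate 1 Prl had 0 counts.

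Striatal tissue in 3xTg vehicle replicate 2 is a candidate explanation for the lower thalamic and striatal markers and neuropeptides in treated mice, with Penk and Drd2 at 165 and 79.8 CPM there; all 14 genes of the marker list passed the filter in these hippocampal libraries, 6 stand in another list and 2 among the neuropeptides. Without that library the median of the first list was -0.185 in place of -1.74 and its camera adjusted p 0.84, so most of it rested on that library. The neuropeptide median was -0.17 in place of -0.585, with a camera adjusted p of 0.0298, and with the choroid and striatum covariates it was -0.0438 (camera adjusted p = 0.141); the list with all libraries had adjusted p = 0.322 with an estimated correlation. Of the other 3xTg vehicle libraries, replicate 1 scored 0.0288, within the treated range of 0.00257 to 0.164, and replicate 3 scored 0.356, so what is left rests on replicate 3, and a treatment effect on it stays open and untested.

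The cholesterol biosynthesis list was lower in treated than in 3xTg vehicle libraries by a median of -0.155. Tissue carried in with the dissection may be weighed by fitting the choroid and striatum scores: the median was then -0.174, which argues against these tissues as the whole cause. A single library is argued against too, since the median nearest 0 over the 6 leave-outs was -0.141, with camera adjusted p under the threshold each time. The list scores argue only weakly against chance values of the 3 shared 3xTg vehicle libraries. The t statistic of 3xTg vehicle against the other 6 was 7.66, and the highest of any of the 42 lists in the other picks of 3 libraries was 6.79 (two-sided exact permutation p = 0.0119 over all lists, the smallest that 84 picks allow). Setting 3xTg vehicle against the other 6 was chosen after the result was seen, which this p does not cover. The test also replaced a first one whose value had been seen. That was the list's own exact p adjusted over the 42 lists (0.5), in which 1 list at the smallest p cannot pass. An effect of genotype lowered by LP-10d stays a hypothesis, since the list did not pass with an estimated correlation (adjusted p = 0.250) and handling shared by the 3xTg vehicle libraries, for which the labels give no batch, is open and untested.

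Treated replicate 2 was WT-like at Gm8210 and Gm21860, noticed in the data, with 0.0593 and 0.83 CPM there, 0.0571 to 0.111 and 0.786 to 1.34 CPM in WT vehicle, and 4.71 to 7.79 and 0 to 0.0568 CPM in the other 3xTg libraries. Mid1 was at 8.72 CPM, between 2.51 to 3.56 CPM in WT vehicle and 14.8 to 40.1 CPM in the other 3xTg libraries. Wdfy1, picked after its values were seen, was at 23.65 CPM, between 12.01 to 20.07 CPM in WT vehicle and 38.83 to 43.19 CPM in the other 3xTg libraries. At Plxnd1 and each gene next in rank in 3xTg vehicle against WT vehicle, treated replicate 2 lay outside the WT vehicle range on the 3xTg vehicle side. Plxnd1 was at 79.14 CPM there (49.41 to 64.61 in WT vehicle), and Sh3bgrl only just outside (58.51 against 58.69 CPM or more). These genes were chosen for separating the 2 groups, so they do not decide the label. A wild-type library with this label and the label's own treated mouse cannot be told apart by the bound set on the genes that separate the groups. On a scale of 0 for WT and 1 for 3xTg vehicle, genes were chosen without the library read. Held-out WT libraries lay at 0.406, 0.518 and 0.122 and replicate 2 at 0.559, 0.641 and 0.497 in the same fits, a smallest gap of 0.123. Replicate 2 thus lay above the held-out WT library in each fit, and treated replicates 1 and 3 lay higher still (0.646 to 0.795). The bound asked for a position above the highest held-out WT library of all fits. It was not met, since 0.497 lies under the 0.518 of another fit, which used other genes. This test replaced a first one after its value was seen: replicate 2 at 0.49 lay above a bound of 0.3, which argued against a WT library, but 2 of the 3 held-out WT libraries lie above that bound too, so it would exclude true WT libraries. Background segments still segregating in the 3xTg line cannot be told apart either. Only 2 genes met the bounds for being WT-like in replicate 2 alone, so the permutation test of neighbours (p = 1) is void. These were Gm8210 on chromosome 1 and Gm21860, annotated on the Y but counted in WT vehicle libraries labelled female. Mid1 spans the pseudoautosomal boundary, and reads shared across it cannot be resolved from gene counts. Whether Gm21860 and Mid1 mark the same segment is therefore open.

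Of the 10 splits of the 6 libraries in each comparison, too few for a share under 0.05, 1, 10 and 10 gave as many called genes as the real split, in the order of the comparisons. The real counts were 1, 0 and 0 and the highest other counts 0, 0 and 0. At an unadjusted p under 0.05 the real counts were 2449, 504 and 1523 and the highest others 1355, 905 and 1336.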
